A study of Escherichia coli with 2 samples.

How the data were processed

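Anti-Flag chromatin immunoprecipitation was sequenced in 2 libraries of Escherichia coli, 1 from a strain with 3xFLAG-tagged bolA and 1 from an untagged strain without the gene. Per the labels' protocols, overnight cultures were diluted 100-fold in LB medium, grown to an OD600 of 0.6, treated with 10 mM sodium phosphate and 1% formaldehyde for 10 min and kept on ice for 30 min. Lysates were sonicated to average sizes between 300 and 700 bp, per the labels' protocols, which sets the resolution of any place named here. Samples were grouped by the strain and genotype labels. Neither the labels nor the files give a further library, an input or a sequencing batch, so strain, tag, library and culture differ together.

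The deposited files hold 1 table per library, with the read count of each window, an RPKM value and the closest gene. The submitters' processing notes name BWA 0.5.9; its settings, the read filters, the treatment of duplicates and the name of the genome build are not given in the sources used here. Per the file headers and values, the authors deposited raw read counts in 92794 windows, 92792 of them 100 bp long, at steps of 50 bp over 4639675 bp. Neighbouring windows overlap, so a read is counted more than once. The deposited counts sum to 51347630 in the tagged library and 52563708 in the deletion library, and 0 windows in either were empty. The RPKM values deposited by the authors equal the count divided by window length and by 1 total per library. That total was 20004271 for the tagged and 25956085 for the deletion library, so the summed counts were 2.57 and 2.03 times it. As a result the deposited RPKM values put the tagged library 1.28-fold above the deletion library at the median window, while its summed counts were 0.977 of the other's. Counts were therefore used, and RPKM only as an alternative.

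Counts per 100 bp were scaled to the same total. The log2 ratio of the tagged to the deletion library was computed with a pseudocount of 10% of each library's median and centred on its median over all windows. It therefore understates large ratios, and folds given with a counting interval carry no pseudocount and are centred on ratios without one. Local log2 values keep the pseudocount. Intervals use windows that do not overlap, with the exact binomial (Clopper-Pearson) method at 95%. Counts over such windows summed to 25669519 in the tagged and 26282487 in the deletion library, each above the total behind its RPKM values. A read may therefore be counted in more than 1 of these windows, which would make the intervals too narrow. Regions were windows at or above a 2-fold ratio and at or above the library's median signal, joined when at most 200 bp apart, and at least 200 bp long. The same rule with the libraries exchanged gave the background. Local values subtract the running median of the log2 ratio over 50 kb, with the chromosome as a circle. Single-copy sequence leaves out windows closest to rRNA, insertion sequence, rhs, tuf, tfa, gadA and gadB genes. With 1 library per group, counts per window were compared by size and no count model was fitted.

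Gene positions and strands came from the files' own distances between windows and genes. They gave the start of 1675 genes, whose value is the mean over windows from 300 bp upstream to 100 bp downstream of the start. The other 2756 genes, often inside operons, were measured over the windows the files assign to them. Of the 4440 names in the files, 9 occur at several places and were left out of gene values. The reference gene table (assembly ASM584v2) was used only to match older names, and none of its coordinates were used. It placed 436 of 437 listed genes, and its table held 4420 of the files' names. The 16 gene lists covered flagellar classes 1 and 2, late flagellar and chemotaxis genes, biofilm matrix, cyclic di-GMP, cell wall, cell division, the TCA cycle, porins, general stress, iron-sulfur clusters and BolA partners, ribosomal proteins, rRNA, tRNA, highly transcribed genes, H-NS-silenced genes, and reported BolA-linked genes. Each list's median was placed among 10000 random lists of the same size matched on deciles of mean signal, and among the same list moved along the gene order. Many members share operons, which the second comparison keeps and the first does not. A gene's counting interval reached, at the median over genes, 0.07 to either side on the log2 scale.

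The design, the lists, the thresholds and the rule for named genes were fixed before the data were examined. That rule takes genes at the 20 largest regions higher with the tag and the 5 largest higher in the deletion strain, bolA and its neighbours, and from each list the 3 highest members and the lowest one. Alternatives covered the pseudocount (1% and 50%), the centring, the fold (1.5 and 4), the signal minimum, the joining distance (0 and 1000 bp), the windows used per gene and the rRNA windows. The region rule was tested on simulated counts with the measured dosage differences and planted regions of 600 bp, 50 at each size, in 92794 windows. With the 2-fold rule it found 0 of 50 regions planted at 1.5-fold, 46% at 2-fold and 100% at 3-fold, with 0 regions elsewhere. With local centring and 1.5-fold it found 66% of those planted at 1.5-fold and 100% at 2-fold, also with 0 elsewhere. The simulated counts varied by counting error only, whereas the measured local log2 ratios had an SD of 0.12, against 0.08 from counting. The simulation therefore does not measure how many false regions these libraries give. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.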

Results

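Chromatin immunoprecipitation followed by sequencing was used to ask where BolA, a small DNA-binding protein of Escherichia coli that affects cell shape, lies on the chromosome. An anti-Flag antibody was applied to 2 cultures: a strain whose bolA gene carried a 3xFLAG tag, and a strain without bolA and without the tag, which served as the control. Cultures were grown in LB medium to an OD600 of 0.6 and cross-linked with 1% formaldehyde. Each group held 1 library, so no value has a replicate error, no p-value is given, and every difference describes these 2 libraries. The files gave read counts in 92794 windows of 100 bp placed every 50 bp along the whole chromosome. The median window held 538 reads in the tagged library and 544 in the deletion library. At that depth counting error alone is 4.31% and 4.29% of a window's count. Counting intervals are exact binomial 95% intervals, and reads are not independent molecules, so these intervals cover counting error at most.

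The bolA gene itself had far fewer reads in the deletion library. It lies on the forward strand at positions 453696 to 454013 of the files' sequence. The 5 windows inside it averaged 741 reads in the tagged library and 116.4 in the deletion library. The scaled ratio was 6.47-fold (95% counting interval 5.85 to 7.47), or a log2 ratio of 2.24 with the pseudocount. Over its left neighbour yajG, a lipoprotein gene, the means were 604 and 608.25 reads, and the fold was 1.01. Over its right neighbour tig, which encodes the chaperone trigger factor, they were 595.893 and 598.321 reads, also 1.01-fold. Over the next gene, clpP, a protease subunit gene, they were 672.5 and 599.5 reads, 1.14-fold (1.09 to 1.18). The deletion library thus had the lower signal at the deleted gene, as its label says, and kept 15.5% of the tagged level there.

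Beyond bolA, flagellar operons were the main places where the tagged library stood above the control. By the size rule fixed before the data were examined, 2 regions were at least 2-fold higher with tagged BolA and 0 were higher in the deletion strain. The first was bolA, at 453501 to 454150. The other covered 1500 bp at 1129501 to 1131000, over flgA, flgB and flgC. The genes flgA and flgB are the first of 2 divergent operons. The operon of flgB includes genes for the basal body, the part of the flagellum anchored in the envelope. At the summit of this region, inside flgB, 971 reads faced 405, a log2 ratio of 1.18. Over flgA, which helps assemble the P ring, the start region averaged 921.2 against 411.7 reads, 2.28-fold (2.15 to 2.39). Over flgB, a rod protein gene, the means were 916.818 and 407.909, 2.29-fold (2.18 to 2.43). Over flgC, another rod protein gene, the log2 ratio was 0.99. The wider flg cluster was 1.80-fold higher at flgN, a chaperone gene, and 1.71-fold higher at flgM, the anti-sigma factor gene. The 2-fold call over flgA to flgC was lost after subtraction of the running median of the log2 ratio over 50 kb, where its summit was at 1.72-fold and a region in fliF was called in its place. The number of regions in this direction moved between 0 and 34 over the alternative settings.

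**Figure D1:**
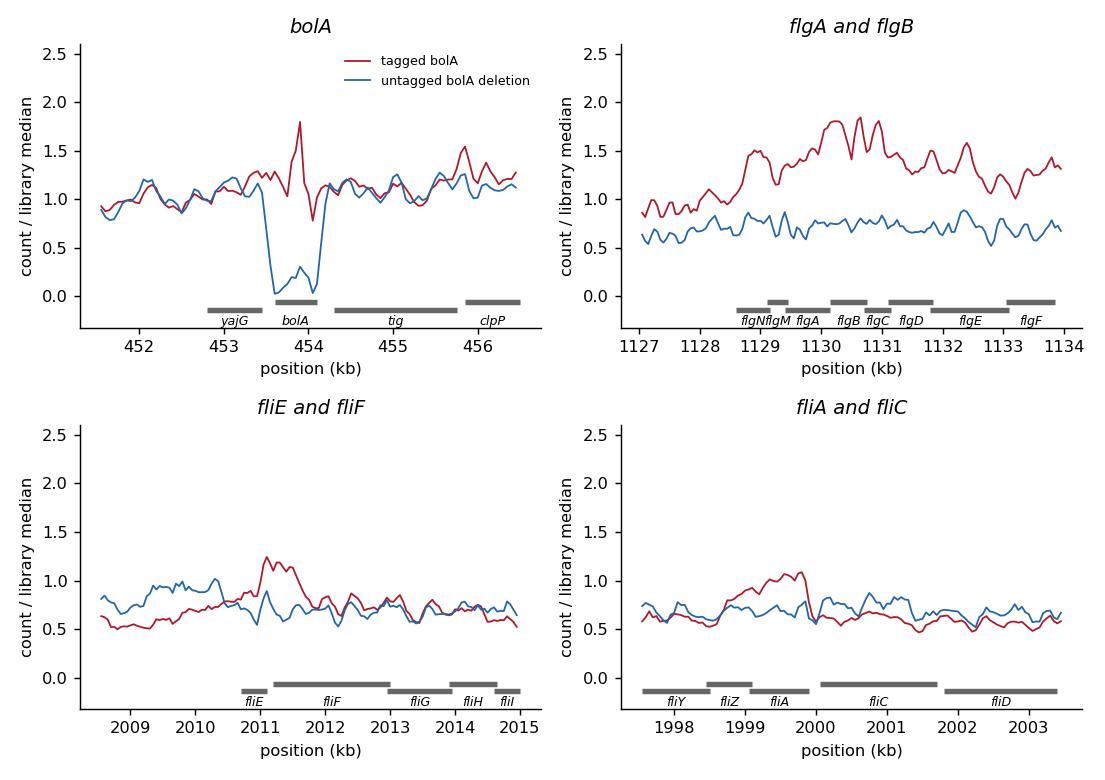
Read count per 100 bp window divided by the library median, against position in kb, for 4 loci, with the tagged library in red, the deletion library in blue and grey bars for the windows annotated to each gene. The blue line is low over bolA and lowest just before the gene start. The red line stands above its own flanks over flgA and flgB, over fliE and fliF and over fliA, and not over fliC.

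The ratio of the libraries also differed between long stretches of the chromosome, which set the level of most genes. From 688 kb to 1607 kb the tagged library was higher, with a median log2 ratio of 0.38 (1.30-fold, SD 0.04 over 91 bins of 10 kb). From 1607 kb to 1682 kb the median was 0.04 (7 bins). From there to 3128 kb the tagged library was lower, with a median of -0.38 (SD 0.06 over 143 bins) and of -0.26 in the first 100 kb. Over the rest of the chromosome the median was 0.02 (SD 0.05 over 220 bins). The rest was not flat: bins centred at 3825, 3925 and 4025 kb had medians of 0.12, 0.13 and 0.11. Those at 125 kb and 3225 kb had 0.00 and -0.005. The outer borders coincided with copies of insH, the transposase gene of an insertion sequence, annotated at 687151 to 688300 and 3128201 to 3129300. With a threshold of 1.5-fold, 30 of the 34 regions higher with tagged BolA lay in the higher stretch. Of the 68 regions higher in the deletion strain, 65 lay between 1609 kb and 3128 kb, the range counted as the lower stretch here. Gene values are therefore given both with 1 centre for the whole chromosome and after subtraction of that running median, called the local value.

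**Figure D2:**
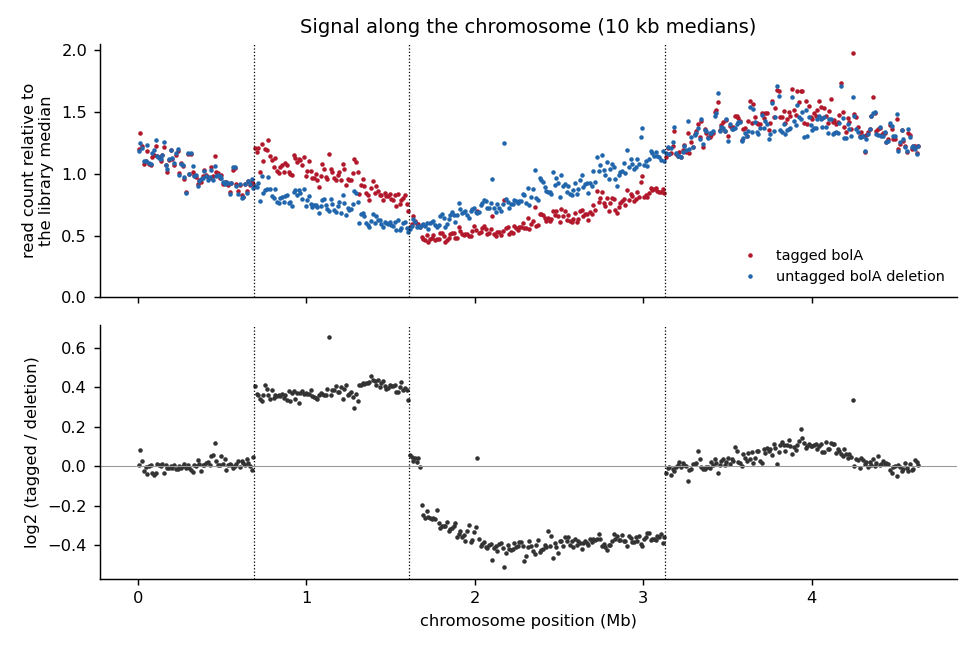
Median read count per 10 kb bin, relative to the library median, against chromosome position in Mb, for the tagged (red) and deletion (blue) libraries, and in the lower panel the log2 ratio of the same bins. Dotted lines mark the 2 insH copies and the position of 1609 kb, and the ratio sits near 0.38 between the first pair of lines, near 0.04 just after 1609 kb, near -0.26 beyond 1682 kb, and at a median of -0.38 from there to the last line.

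With local values, a 1.5-fold threshold and a signal minimum at the local median, an alternative chosen after seeing the data, 7 regions of single-copy sequence were higher with tagged BolA and 0 were higher in the deletion strain. Flagellar genes made up 5 of the 7, the others being bolA and a region beside uxaB. The strongest flagellar region lay at 2010751 to 2011750, between and over the divergent genes fliE and fliF, which encode a hook-basal body protein and the MS ring. Its summit held 613 against 315 reads, a local log2 value of 1.18. The region over fliA, the flagellar sigma factor gene, and fliZ reached 0.92. The region over fliL and fliM, a motor-associated gene and a switch gene, reached 0.87, and flgA to flgC reached 0.78. The region over flhB, an export gate gene, reached 0.74. The last region, at 1607051 to 1607250 beside uxaB, reached 0.73 and lay at a border between stretches, where the running median is least apt. These places were named after their values were seen. Without the single-copy filter and the local minimum, 7 regions were higher with tagged BolA and 6 in the deletion strain. All 6 lay in rRNA or insH copies.

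Among the gene lists fixed beforehand, the flagellar regulator and secretion-motor list (classes 1 and 2 of the flagellar hierarchy) stood apart most by local value. All 31 measured members had local values above 0, whereas with the chromosome-wide centre 19 were above 0 and 12 below. Many of these members lie side by side in shared operons, so they are not 31 separate places. By local value, which keeps the pseudocount, 6 were at least 1.5-fold higher. Without the pseudocount fliM, at 1.52-fold, also reached that size. The median local log2 ratio was 0.35. It lay at percentile 100 both among 10000 random lists matched on mean signal and among the same list moved along the chromosome. By local value, and so chosen after their values were seen, the highest members were fliF at 2.07-fold (1.99 to 2.23) and fliE at 2.02-fold, which share most of their windows. They were followed by fliL at 1.72-fold (1.68 to 1.87), flgB at 1.68-fold (1.60 to 1.78) and flgA at 1.67-fold (1.58 to 1.75), the order of these 3 being different with the pseudocount. The lowest member by the chromosome-wide value was flhC, part of the master regulator, with a log2 ratio of -0.28 chromosome-wide and 1.05-fold locally (1.01 to 1.14). With the chromosome-wide centre the list's median was 0.15. That median lay at percentile 99.9 among matched lists and 80.1 among moved lists, with 10 members in the higher stretch and 21 in the lower one.

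Late flagellar and chemotaxis genes did not share that level. Of 23 members, 13 had local values above 0 and 10 below, 0 were 1.5-fold higher, and the median was 0.02 (percentile 94.3 among matched lists). Members with the highest chromosome-wide values included flgN at 1.32-fold and flgM at 1.25-fold locally, both inside the flg cluster. The start region of fliC, the flagellin gene (named after its value was seen), averaged 314 against 364.9 reads, a local 1.11-fold (1.04 to 1.19), with a log2 ratio of -0.17 chromosome-wide. The lowest, cheW, a chemotaxis coupling protein gene, was at 0.92 of the control locally (0.87 to 1.00).

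**Figure D3:**
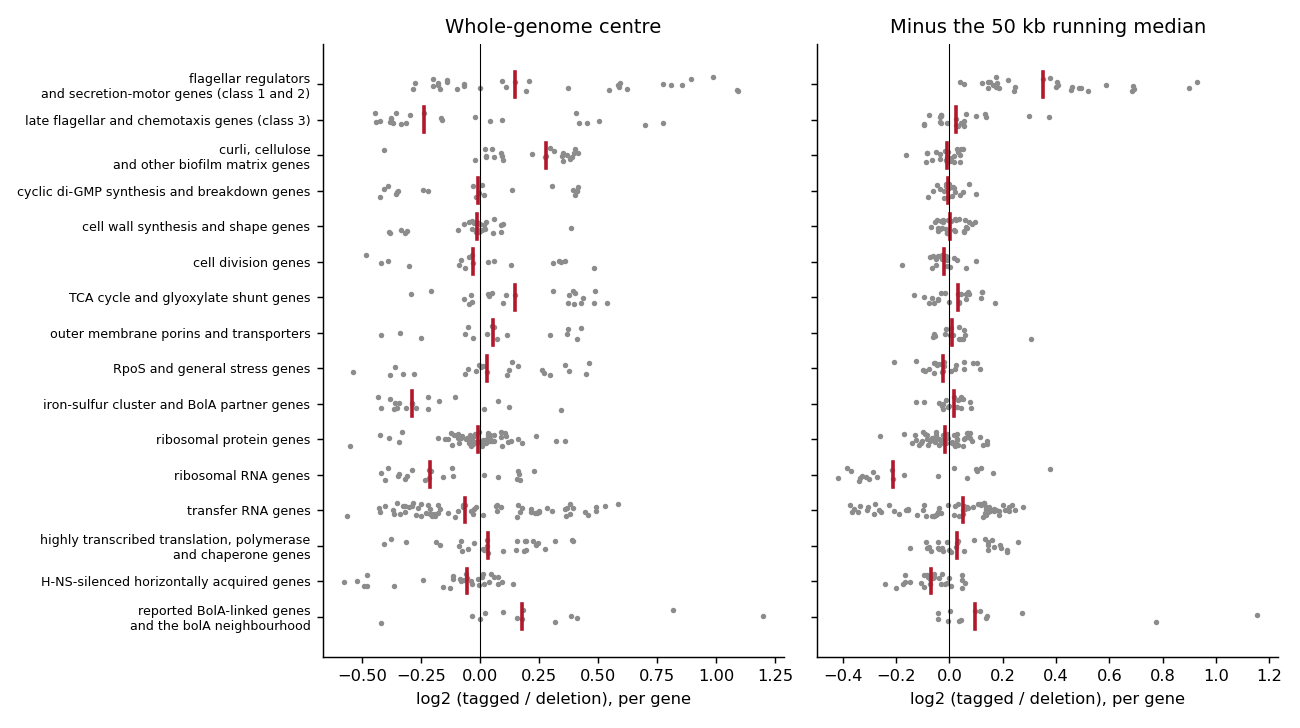
Log2 ratio of the tagged to the deletion library per gene (grey points, spread vertically for visibility) and the list median (red bars) for the 16 gene lists, centred on the whole chromosome on the left and minus the running median over 50 kb on the right. On the right only the class 1 and 2 flagellar list has every member above 0, with a median of 0.35.

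The biofilm matrix list gave no local difference. Its 24 measured members, among them the curli and cellulose genes, had a median log2 ratio of 0.28 with the chromosome-wide centre, at percentile 100 among matched lists. However, 14 of them lie in the higher stretch, and the local median was -0.01 (percentile 27.7). The start region of csgD, the curli and biofilm regulator gene (named after its value was seen), was at 0.93 of the control locally (0.90 to 1.00). The members with the highest chromosome-wide values, the biofilm regulators bssS and bssR and the polysaccharide gene pgaD, had log2 ratios of 0.41, 0.40 and 0.40 and local values of 0.02, 0.05 and 0.04. The lowest, flu, a surface adhesin gene, had -0.41 and -0.02. Genes that make or break cyclic di-GMP, the second messenger of the switch from motility to biofilm, had a local median of 0.00 (percentile 34.4).

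Central metabolism and stress genes lay close to their surroundings. The list of TCA cycle genes had a chromosome-wide median of 0.15 and a local median of 0.03. The local median lay at percentile 98.9 among matched lists and 96.8 among moved lists. Its members with the highest chromosome-wide values were sucA at 1.14-fold locally (1.09 to 1.21), sdhB at 1.10-fold and sucB at 1.09-fold, all from 1 cluster. The fumarate reductase genes, from another operon and named after their values were seen, lay on both sides of the control locally. Of these, frdD was at 1.09-fold (1.05 to 1.15) and frdA at 1.05-fold, but frdB was at 0.93 (0.91 to 0.97) and frdC at 0.95. The lowest of the list was fumA at a local log2 value of -0.13. General stress genes had a local median of -0.03 (percentile 5.12), with otsB, a trehalose synthesis gene, lowest at 0.84 of the control (0.80 to 0.90). Iron-sulfur cluster genes and genes of BolA partners had a median of -0.29 chromosome-wide, with 14 of 19 in the lower stretch, and 0.02 locally (percentile 86.2).

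Cell wall and shape genes had a local median of 0.00 (percentile 50.0) over 28 members. The start region of mreB, the actin-like shape gene, was 1.07-fold higher locally (1.02 to 1.11). The penicillin-binding protein gene dacC had a local log2 value of 0.04 and slt one of 0.07. Cell division genes had a local median of -0.02, with minC highest at 0.10 and sdiA lowest at -0.18. In the list of reported BolA-linked genes with the bolA neighbourhood, the local median was 0.10 over 13 members, 10 of them above 0, at percentile 100 among matched lists and 99.5 among moved lists. The start regions of bolA, yajG and tig reach into the deleted stretch, which sets part of these values. Without these 3, an alternative chosen after seeing the data, the local median was 0.04 over 10 members, at percentiles 96.6 among matched lists and 94.97 among moved lists. Porin genes had a local median of 0.01, with ompF at 0.04 and ompC at 0.00.

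Genes that immunoprecipitations tend to recover without a tag gave a background for these values. Ribosomal protein genes had a local median of -0.02 over 54 members (percentile 8.49 among matched lists and 4.06 among moved lists). Highly transcribed translation, polymerase and chaperone genes had 0.03 over 29 members (percentile 97.1 among matched lists and 97.9 among moved lists). Of that list 17 members were above 0 locally and 12 below. Among members named after their values were seen, the chaperonin genes groL and groS were at 1.21-fold (1.17 to 1.23) and 1.17-fold (1.14 to 1.24), and the disaggregase gene clpB at 1.16-fold locally (1.14 to 1.20) but at a log2 ratio of -0.17 chromosome-wide. The RNA polymerase gene rpoB was at 0.97 of the control locally (0.94 to 1.01). Transfer RNA genes had 0.05 over 69 members (percentile 100). Ribosomal RNA genes had -0.21 over 22 members, and reads from their near-identical copies cannot be placed with certainty. By gene type, a split made after the values were seen, the start regions of all 7 16S genes were above 0 locally (median 0.11). All 7 23S genes were below 0 (median -0.30), and 7 of 8 5S genes were below 0 (median -0.26). Inside the genes, the 229 windows of 16S sequence had a median of -0.17 chromosome-wide and the 420 of 23S sequence -0.37. The excess at 16S start regions was therefore not shared by the 16S genes as a whole. H-NS-silenced genes, which are AT-rich and acquired from other bacteria, had -0.07, with 25 of 30 members below 0 (percentile 0).

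Much of the tagged profile's pattern was also present without the tag. Across windows the signals of the 2 libraries had a Pearson r of 0.85 and a Spearman rho of 0.82. Windows overlap and are not replicates. The SD of the window log2 ratio was 0.29 with the chromosome-wide centre and 0.12 with local values, while counting error alone gives 0.08. The summits of both 2-fold regions lay between genes or within 300 bp upstream of a gene start, but the place of the bolA summit is set by the deletion, and 1 other region gives no usable share. Of the 34 regions at 1.5-fold, 10 had such a summit (29.4%, exact interval 15.1% to 47.5%), against 12.8% of all windows, and 30 of the 34 lay in the higher stretch.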

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

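No paired analysis was possible because each group has 1 library; for the same reason no library could be left out. None of the 117 recomputed values has a test. By fixed limits (for list medians, the interval from resampled members), 93 were within them, 22 beyond and 2 reversed; wide intervals make this tally lenient for lists. The number of regions higher with tagged BolA (2) became 6 with a 1% pseudocount, 1 with a 50% pseudocount, 18 with deposited RPKM not centred (16 of them in the higher stretch), 34 at 1.5-fold, 1 at 4-fold, 0 at 2 times the median signal and 4 when only adjacent windows were joined. Alternatives chosen after seeing the data gave 7 with local centring at 1.5-fold, 6 without multi-copy sequence, 7 with a local signal minimum as well, and 1 with bolA left out. The number higher in the deletion strain (0) became 68 at 1.5-fold and 6 with local centring at 1.5-fold, all 6 in rRNA or insH copies. The log2 ratio over bolA (2.24) was 2.64 and 1.40 with pseudocounts of 1% and 50%, and 2.59 with RPKM. Local centring turned the sign of 6 of 16 list medians: the biofilm matrix list (0.28 to -0.0074), the iron-sulfur list (-0.29 to 0.018), general stress (0.03 to -0.025) and, within their intervals, late flagellar (-0.24 to 0.024), tRNA (-0.06 to 0.05) and cell wall genes (-0.01 to 0.00). The TCA median went from 0.15 to 0.033 and that of class 1 and 2 flagellar genes from 0.15 to 0.35. The 2 regions at 2-fold became bolA and fliF, without flgA to flgC. The iron-sulfur median was -0.17 with a 50% pseudocount. Local centring also brought the SD of window ratios to 0.12 and their 1st and 99th percentiles to -0.29 and 0.29. Depth limits single genes to about 0.07 on the log2 scale, and differences between cultures cannot be measured here.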

Other observations

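All tests in this part were chosen after the patterns were seen. For those of the predicted shift between stretches and of extra bolA sequence, the outcome was predicted before it was computed.

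Outside the flagellar genes, a few other places were higher in the tagged library locally, all named after their values were seen. At malK, a maltose transport ATPase gene, the start region averaged 1170 against 816.7 reads, a local 1.39-fold (1.32 to 1.43), and the outer membrane maltoporin gene lamB in the same operon was 1.25-fold higher (1.22 to 1.27). Single windows reached 1.45-fold inside the chaperone gene dnaK (980 against 663 reads) and 1.53-fold inside fabB, a fatty acid synthesis gene (613 against 524 reads). In the other direction, 6 of the 7 copies of the 23S rRNA gene had local medians from -0.46 to -0.35. The copy inside the lower stretch, rrlG, was at -0.03, because the level of that stretch was subtracted. Its mean counts of 1007.87 against 1371.67 reads were close to those of other copies, such as rrlH at 1016.72 against 1370.97. The window beside rseX, a small RNA gene, held 206 against 478 reads, and one beside yffQ, a prophage gene, 854 against 1663. Locally the deletion library was 1.57-fold and 1.44-fold higher at these 2 windows.

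At the 2 insH copies the log2 ratio along the chromosome stepped by 0.38 and 0.35, against a 99th percentile of 0.17 in size over 4277 positions away from the 3 steps, the largest of these being 0.28 in size at 1685 kb, beside the rstB border described separately. The steps were in the tagged library (0.36 and 0.45), not in the deletion library (-0.06 and 0.05), and neither a difference in library depth or scaling nor a difference in replication rate between the cultures would give steps. A candidate explanation is an inversion of the 2.44 Mb between these insH copies, which would bring 1 inner stretch closer to the replication origin and take the other farther away by 0.609 Mb. The deletion library's own gradient of -0.61 log2 units per Mb then predicts shifts of 0.37, and the observed shifts of 0.36 and -0.39 average 1.02 times that prediction. Read pairs or junction reads were not used here, and whether the change arose in the parent or during strain construction was not tested.

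The middle border of these stretches had 2 steps rather than 1, with a median log2 ratio of 0.04 between them, a level that was not part of the prediction. The tagged library's log2 signal fell by 0.37 at the uxaB window (1607151 to 1607250) and by 0.27 at the rstB window (1682151 to 1682250), against changes of 0.00 and 0.06 in the deletion library. At both windows the log2 ratio was also above the higher of the neighbouring levels, by 0.59 and 0.56. These genes lie in the region where replication forks meet and are stopped at Ter sites.

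The higher signal over early flagellar operons in the tagged library was not what the stretches alone would give, since the local median of the class 1 and 2 list was 0.35 against a range of -0.03 to 0.03 for the middle 95% of lists moved along the chromosome. General recovery of highly transcribed DNA is argued against as the whole cause by the ribosomal protein genes, at -0.017, although tRNA genes were at 0.05, the start regions of 16S rRNA genes at 0.11 and the list of highly transcribed genes at 0.03, with the chaperonin gene groL at 1.21-fold. Different flagellar transcription in the 2 strains cannot be told apart from recruitment of tagged BolA. The late flagellar list was at 0.024, with members on both sides of 0. Flagellar activity was not measured, and any difference in it would go together with strain and tag here. BolA bound at early flagellar operons or carried there by another protein may therefore account for the signal, as may a difference in flagellar activity between strains. The signal was not limited to promoters, since the summits in fliA, fliL and flhB lay inside genes. In the flg cluster the local excess reached beyond the first genes, at 1.68-fold at flgB, 1.45-fold at flgD, 1.41-fold at flgG and 1.12-fold at flgI.

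The deletion library held reads over bolA, and their share of the tagged count was uneven. It was 2.12% (1.18 to 3.52) in the window at 453551 to 453650, just before the gene start, and 20.7% (17.0 to 25.0) at 453901 to 454000 inside the gene. Uniform carry-over of DNA with an intact bolA gene, from the other library or other cells, would give 1 share throughout and so could account for no more than the lower value. Extra copies of the bolA coding sequence in both libraries, such as from a plasmid or amplified DNA, may account for the rest: inside bolA the tagged library exceeded its own flanks by 1.27-fold, 2.04 SD of the same quantity across the chromosome. That excess is small and uneven: the 5 windows inside the gene held 555, 746, 809, 967 and 628 tagged reads. Over yajG and tig the tagged means were 604 and 595.893 reads. Sequence-dependent recovery or BolA at its own gene remains open.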
